A study of Rattus norvegicus with 12 samples.

How the data were processed

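Total RNA from rat knee articular cartilage was hybridized to 1-colour Affymetrix arrays with a biotin label. The 12 arrays fell into 4 groups of 3, namely surgery that induces osteoarthritis (OA) or sham surgery, each at 2 and at 8 weeks after surgery. The labels number the arrays of a group from 1 to 3 and do not say whether they come from separate animals, so the p-values measure only the spread between samples. The number of arrays limits the precision of every value.

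The values used were the deposited log2 values of 31099 probe sets, which the authors had background corrected, normalized between arrays and summarized with GCRMA, whose version is not stated. They were used without further normalization. No fold change against a zero arises on this scale, but GCRMA values near the floor compress differences.

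Gene symbols came from the annotation of the array, checked against the current table of rat genes. Of all probe sets, 20832 carried exactly 1 symbol, 436 carried several and 9831 carried none, the 57 control probe sets among them. The Entrez gene ID of 20764 probe sets was in the current table, and the update changed 0 symbols. The 20832 probe sets stood for 14218 distinct symbols.

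Control probe sets were left out, and the others were kept if their log2 value exceeded 4 in at least 3 of the 12 arrays, whatever the group. This filter kept 15934 probe sets and left out 15108. For values per gene, the kept probe set with exactly 1 symbol and the highest mean over the 12 arrays was used, which gave 9247 genes.

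A linear model with 1 mean per group was fitted to each kept probe set with limma 3.58.1 in R 4.3.3, with empirical Bayes variances (8 residual and 1.94 prior degrees of freedom). A change was called at a Benjamini-Hochberg adjusted p under 0.05 over the 15934 probe sets. The comparisons were OA minus sham at 2 weeks, OA minus sham at 8 weeks, the average of both, the difference between both (the interaction), and 8 minus 2 weeks within sham. In the OA comparisons, rose and fell mean higher and lower in OA than in sham, not a change over time. Errors beside log2 differences are standard errors from this model, with 3 arrays per group. The model takes 1 spread per probe set for all 4 groups. Where the 8-week arrays varied more than the 2-week arrays, these errors tend to be too small for 8-week and too large for 2-week differences. Mmp13 is an example, with SDs of 1.10 in OA and 0.46 in sham at 8 weeks, against 0.37 and 0.11 at 2 weeks. The same held in both groups for Itga8, Ppargc1a, G0s2, Nr3c2, Cd68, Rassf4, Cfd, Gfap and Clec4a, named below for large 8-week changes. The 8-week errors given for these genes therefore tend to be too small. Among the other genes picked for the largest 8-week changes, Cpxm1 had smaller SDs at 8 weeks in both groups. For Tgfa, Anks1b, Lhfpl3, Nr4a2, Pltp and Cldn11 the SD was larger at 8 weeks in only 1 group. How often the spread was larger at 8 weeks over the 15934 probe sets was not tested. The tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

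A total of 33 gene lists (cartilage tissue, disease processes, pathways and markers of other cell types) were tested with limma's camera, with a preset correlation of 0.01 between genes and adjustment over the lists within a comparison. Camera compares the genes of a list with all other genes. Each list was also tested with a correlation estimated from the data, on ranks, and with fry, a rotation test of the list's own genes. The lists held 796 distinct genes, of which 701 had a probe set with exactly 1 symbol and 522 passed the filter.

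The lists, comparisons, tests, filter and most alternatives were fixed before the data were examined, and so was the rule for which genes are named. For the OA comparisons at each time and averaged, it took up to 8 genes with the largest rise and 8 with the largest fall among those called whose 3 OA arrays all lay on one side of the 3 sham arrays (at both times for the average). For the interaction and the sham comparison it took the 5 largest called changes in each direction. Where fewer passed, up to 4 genes with the smallest unadjusted p were added in that direction, given as values that did not pass. The rule further took the 2 to 4 members of each described list with the smallest unadjusted p, and 12 genes of interest in both OA comparisons, of which 3 are not reported singly here. These 12 were textbook cartilage genes and genes picked from the knowledge that the laboratory studied TGF-alpha and CCL2 in this model. They are therefore not a blind choice. Symbols that start with LOC or RGD were counted and not named. Genes named outside this rule are said to be chosen after their values were seen.

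The alternatives changed 1 choice at a time. They were no filter, a filter at log2 6, added quantile normalization, equalized array medians, array weights, a variance trend with and without robust estimation, the replicate number as a block, 1 probe set or the mean of the probe sets per gene, a threshold of 2-fold or of 0.1, only the 6 arrays compared, and each of the 12 arrays left out in turn. After the data had been seen, 3 more were added, namely a replicate block within each time, the fit without both number 1 arrays of 8 weeks, and the mean level of the muscle markers as a covariate.

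RNA and array quality were described from the control probe sets. Differences between 3 OA and 3 sham arrays in these measures were tested with two-sided exact permutation tests, whose smallest possible p is 0.1.

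The model was tested on simulated data with the means and spreads of these 15934 probe sets, in 5 simulations per comparison. For OA against sham at 2 weeks, 63.6% of 100 probe sets changed by 1 on the log2 scale and 91.0% of 100 changed by 2 were recovered per simulation on average, and 5.50% of the calls were false. For OA against sham at 8 weeks the shares were 65.6% and 91.0%, with 4.51% false calls, and for time within sham 65.2% and 90.6%, with 6.26% false calls. A list of 46 genes raised by 1 on the log2 scale at 8 weeks, tested among 9247 genes, was found in 5 of 5 simulations by camera, by camera with an estimated correlation and by fry. These simulations drew genes independently, so they say nothing about lists whose genes vary together. They also gave each probe set the same spread in all groups and drew arrays independently. The shares need not hold where the groups differ in spread or arrays deviate together.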

Results

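Gene expression was measured in knee articular cartilage of rats after surgery that induces osteoarthritis (OA) or after sham surgery, with 3 arrays per group at 2 weeks and 3 per group at 8 weeks. Between 48.2% and 49.8% of the probe sets of an array lay above a log2 value of 4. The mean correlation of an array with the others of its group ranged from 0.973 (sham 8 weeks replicate 1) to 0.988 (sham 2 weeks replicate 2). The first principal component held 57.4% of the variance and parted the 2-week from the 8-week arrays, and the second held 12.7%.

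The comparison of OA with sham at 8 weeks addressed which cartilage genes differ in the later of the sampled stages. Tgfa, which encodes the EGF receptor ligand transforming growth factor alpha, rose by 3.02 ± 0.15 on the log2 scale (8.13-fold, adjusted p = 2.58e-05), the smallest p of all probe sets. Mmp3, which encodes the matrix-degrading enzyme stromelysin 1, was higher in OA by 1.57 ± 0.14, with means of 14.93 in OA and 13.36 in sham. Mmp13, which encodes a collagenase that cleaves type II collagen, fell by 2.51 ± 0.46 (5.68-fold lower, adjusted p = 0.0219), a call that ended with the level of muscle markers as a covariate, chosen after seeing the data (0.229), or with only the 6 arrays compared (0.146). Cd68, a macrophage and lysosome gene, fell from a mean of 9.01 in sham to 2.54 in OA (-6.46 ± 0.45, adjusted p = 0.000172). The OA mean lay under the filter level of log2 4, so the size of the fall is not exact. Of 15934 probe sets, 552 passed the limma test, 241 higher and 311 lower in OA. At the level of 1 probe set per gene, 95 genes rose and 227 fell.

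**Figure D1:**
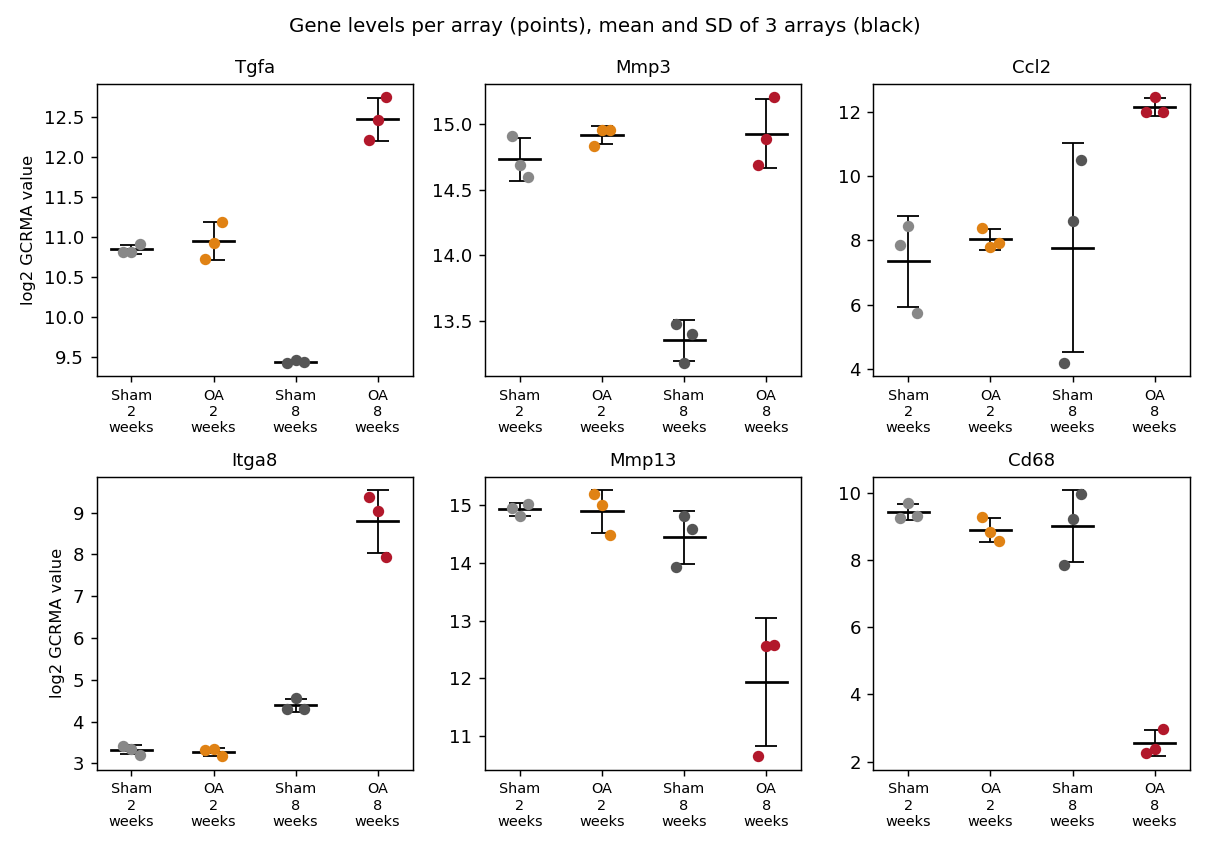
Log2 GCRMA values of 6 genes in each of the 12 arrays (points, 3 per group), with the group mean (horizontal bar) and SD (error bar) in black. At 8 weeks Tgfa averaged 12.47 in OA and 9.45 in sham, Cd68 averaged 2.54 and 9.01, and the 3 sham arrays of Ccl2 lay between 4.18 and 10.51.

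Itga8, the integrin alpha 8 subunit, rose by 4.39 ± 0.29 at 8 weeks (adjusted p = 0.000172), from a sham mean of 4.40. Ppargc1a, a coactivator of mitochondrial genes, rose by 3.96 ± 0.62 (adjusted p = 0.0126), while its other probe set differed by 0.43 and did not pass. Anks1b rose by 2.82 ± 0.45, and 3 of its 3 probe sets passed. Lhfpl3 rose by 2.60 ± 0.20, and the nuclear receptor gene Nr4a2 by 2.48 ± 0.36. G0s2, an inhibitor of lipolysis, rose by 2.46 ± 0.32, and Nr3c2, the mineralocorticoid receptor, by 2.45 ± 0.36. The lipid transfer protein gene Pltp (-4.95 ± 0.84), Rassf4 (-4.61 ± 0.47), the complement factor D gene Cfd (-4.53 ± 0.55) and Cpxm1 (-4.33 ± 0.65) fell. Gfap (-4.32 ± 0.47), the tight junction gene Cldn11 (-4.10 ± 0.79) and the myeloid lectin gene Clec4a (-3.96 ± 0.67) also fell. The mean of 1 of the 8-week groups lay under log2 4 for Ppargc1a, Cd68, Cfd and Cpxm1, a range in which array values do not give the size of a difference exactly, so these genes are not ranked by it. Of the genes first named here, only Itga8 and Lhfpl3 kept their calls both with the muscle covariate and with only the 6 arrays compared. A second, dimmer probe set of Tgfa differed by -0.17 ± 0.53 (adjusted p = 0.897).

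Of the genes chosen in advance, Ccl2, a chemokine that attracts monocytes, was higher in OA at 8 weeks by 4.38 ± 1.31 without passing the test (adjusted p = 0.0994). Its 3 sham arrays read 4.18, 8.61 and 10.51 and its 3 OA arrays 11.98, 12.46 and 11.99. Its receptor gene Ccr2 did not exceed 2.51 in any array and was left out by the filter. The EGF receptor gene Egfr differed by -0.20 ± 0.46, the aggrecanase gene Adamts5 by -0.16 ± 0.50 and the hypertrophy gene Col10a1 by -0.07 ± 0.12. The main cartilage collagen gene Col2a1 differed by -0.20 ± 0.08 (adjusted p = 0.196) and the aggrecan gene Acan by 0.22 ± 0.11 (adjusted p = 0.271). Of these, Ccl2, Egfr, Adamts5, Col10a1, Col2a1 and Acan were tested with limma and did not pass. Col2a1, with 8-week means of 16.00 in OA and 16.20 in sham, read close to the highest values of the arrays. A difference may be compressed there, so its small size does not show that its level was unchanged.

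Among 7 measured EGF family ligands and receptors, 2 rose and 0 fell, namely Tgfa and Adam17, whose product sheds EGF receptor ligands from the cell surface (0.97 ± 0.14). Adjusted over the list alone, 3 rose and 1 fell, with Egf at 0.81 ± 0.21 and Hbegf at -1.04 ± 0.31. Camera called the list higher (median 0.23, adjusted p = 0.00454), with adjusted p = 0.253 with an estimated correlation, and fry gave 0.000415. Camera on ranks gave 0.114 for the EGF family ligands and receptors. Among 12 ERK pathway target genes, 1 rose, the feedback inhibitor gene Spry2 (1.02 ± 0.23), and 0 fell (median 0.04, adjusted p = 0.633).

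Of 27 matrix proteases, 2 rose (Mmp3 and Adam17) and 4 fell. Those that fell were Mmp13, the gelatinase gene Mmp9 (-3.62 ± 0.45), the bone-resorbing protease gene Ctsk (-1.31 ± 0.16) and Adamts9 (-2.51), which was named after the values were seen. Adjusted over the list alone, 2 rose and 6 fell. The list as a whole was lower (median -0.38, adjusted p = 0.0261; adjusted p = 0.606 with an estimated correlation; fry 0.116). This call ended without OA 8 weeks replicate 1 (0.0875 for the matrix proteases), sham 8 weeks replicate 2 (0.199) or sham 8 weeks replicate 3 (0.0541). Among 16 protease inhibitors, 0 rose and 1 fell, the collagen chaperone gene Serpinh1 (-0.54 ± 0.10), with 2 higher and 2 lower when adjusted over the list alone. Their median was -0.10, their mean 0.01 and camera pointed down (adjusted p = 0.867).

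Of 26 cartilage matrix genes, 4 fell and 0 rose, both over all genes and adjusted over the list alone. They were the type IX collagen genes Col9a1 (-0.48 ± 0.10), Col9a2 (-1.04 ± 0.20) and Col9a3 (-0.60 ± 0.10) and the proteoglycan gene Bgn (-0.52 ± 0.11). The cartilage matrix list was lower (median -0.17, adjusted p = 0.0323; adjusted p = 0.571 with an estimated correlation; fry 0.0529). Without OA 8 weeks replicate 1, sham 8 weeks replicate 1 or sham 8 weeks replicate 2, its adjusted p was 0.128, 0.178 or 0.0633, and with added quantile normalization it was 0.130. Of 12 chondrocyte transcription factors and receptors, 2 fell over all genes and adjusted over the list alone, the parathyroid hormone receptor gene Pth1r (-0.85 ± 0.18) and Nfatc2 (-1.20 ± 0.28), and the list did not pass (0.701). Of 20 hypertrophy and mineralization genes, Vegfa rose (0.57 ± 0.12) and Dmp1 fell (-2.22 ± 0.39), with 2 higher and 4 lower when adjusted over the list alone (median -0.10, adjusted p = 0.633). None of 14 superficial zone genes passed (median 0.06, adjusted p = 0.565).

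Of 46 fibrous and repair matrix genes, 1 rose and 6 fell. The short-chain collagen gene Col8a1 rose (1.02 ± 0.21), and the microfibril gene Mfap2 (-2.53 ± 0.23), the WNT-induced gene Ccn4 (-1.39 ± 0.23) and Col16a1 (-0.69 ± 0.12) fell. Adjusted over the list alone, 1 rose and 9 fell. A total of 37 of the 46 genes were lower (median -0.45, adjusted p = 0.000256; adjusted p = 0.497 with an estimated correlation; fry 0.0337).

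Markers of macrophages and bone cells were lower in OA at 8 weeks. All 19 measured macrophage markers were lower (median -2.29, adjusted p = 2.32e-08; adjusted p = 0.497 with an estimated correlation; fry 0.0319). Of these 19, 4 fell over all genes and 12 adjusted over the list alone, among them Cd68, Laptm5 (-2.54 ± 0.32), the colony-stimulating factor receptor gene Csf1r (-1.93 ± 0.27) and the antigen presentation gene Cd74 (-3.38 ± 0.71). Of 7 osteoclast markers, 5 fell over all genes and over the list alone, namely Mmp9, Ctsk, the integrin gene Itgb3 (-3.46 ± 0.48), the acid phosphatase gene Acp5 (-2.53 ± 0.36) and the proton pump gene Tcirg1 (-0.85), the last of these named after the values were seen. The osteoclast list was lower (median -1.31, adjusted p = 9.7e-05; adjusted p = 0.447 with an estimated correlation; fry 0.00318). All 11 osteoblast and osteocyte markers were lower (median -1.13, adjusted p = 5.3e-06; adjusted p = 0.253 with an estimated correlation; fry 0.00318). Of these 11, Phex (-2.53 ± 0.38), Dmp1 and Smpd3 (-1.13 ± 0.23) fell over all genes, and 9 adjusted over the list alone. Mmp9 and Ctsk stand in both the protease and the osteoclast list, and Dmp1 in both the hypertrophy and the osteoblast list. The macrophage, osteoclast and osteoblast calls held with each of the 12 arrays left out in turn.

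Markers of skeletal muscle were higher in OA at 8 weeks, 17 of 18 of them (median 4.25, adjusted p = 7.48e-07; adjusted p = 0.497 with an estimated correlation; fry 0.0856), although 0 of the 18 passed limma over all genes or adjusted over the list alone. Examples are the sarcomere genes Neb (5.84 ± 1.61), Mybpc2 (5.76 ± 1.67) and Ttn (5.67 ± 1.76). The mean level of the muscle markers, centred within each time, was 4.57, 1.28 and -0.21 in the 3 OA arrays and 0.54, -4.11 and -2.07 in the 3 sham arrays. The array at 4.57, OA 8 weeks replicate 1, also stood apart in its control probe sets, with a 3-prime minus 5-prime difference of 0.885 for Gapdh (1.24 to 1.47 in the other arrays) and 5.38 for actin (7.72 to 8.66), and a mean of 9.95 for the hybridization controls (10.7 to 11.5). The corresponding macrophage levels were -1.40, -1.09 and -1.21 in OA and -0.47, 1.80 and 2.37 in sham. With the muscle level as a covariate, an alternative chosen after seeing the data, 48 probe sets passed in place of 552. This level was itself higher in OA by 3.76 at 8 weeks, so the covariate overlaps the tested effect and widens its error. A call that ends with it does not show that muscle accounts for the difference.

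**Figure D2:**
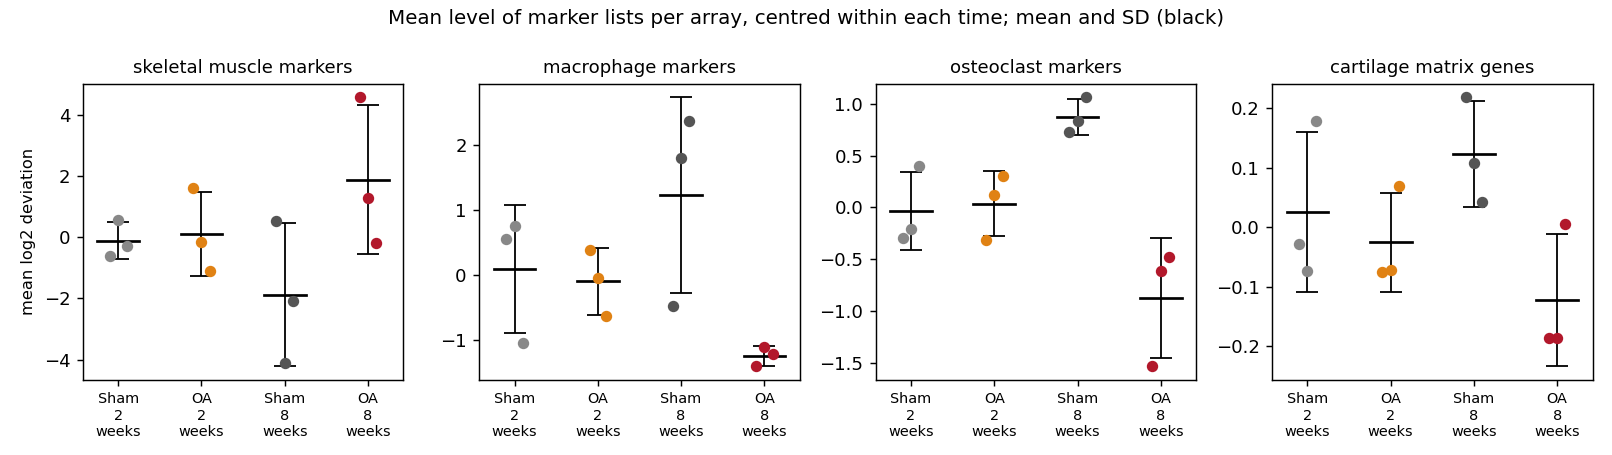
Mean log2 level of the genes of 4 marker lists in each array (points, 3 per group), centred within each time, with the group mean (bar) and SD (error bar). At 8 weeks the macrophage level lay between -1.40 and -1.09 in OA and between -0.47 and 2.37 in sham, and the muscle level between -0.21 and 4.57 in OA and between -4.11 and 0.54 in sham.

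Among 32 hypoxia and glycolysis genes, 6 rose and 0 fell, with 7 and 0 adjusted over the list alone. They included the oxygen sensor gene Egln3 (1.46 ± 0.26), the oxidoreductase gene Ero1a (0.74 ± 0.15), Mxi1 (0.67 ± 0.14) and the angiogenic factor gene Vegfa (0.57 ± 0.12). The list was higher (median 0.11, adjusted p = 0.000881; adjusted p = 0.497 with an estimated correlation; fry 0.0577). Of 22 immediate early and heat shock genes, Nr4a2 rose and 0 fell, with 4 higher and 3 lower over the list alone (median 0.22, adjusted p = 0.0058; adjusted p = 0.447 with an estimated correlation; fry 0.0577). This call ended without OA 8 weeks replicate 2 (0.0516 for the immediate early and heat shock genes). Of 30 oxidative phosphorylation genes, 0 passed (median 0.01, adjusted p = 0.637).

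Of 30 cell cycle genes, 29 were lower in OA at 8 weeks (median -1.04, adjusted p = 2.18e-05; adjusted p = 0.523 with an estimated correlation; fry 0.0785). The helicase gene Mcm6 fell over all genes (-0.90 ± 0.21), and 9 genes fell when adjusted over the list alone, with Top2a at -1.63 ± 0.45 and Melk at -2.14 ± 0.57. Of 26 genes of the unfolded protein response and secretion, 22 were lower (median -0.22, adjusted p = 0.00454; adjusted p = 0.497 with an estimated correlation; fry 0.0495). Over all genes the growth factor gene Manf fell (-0.47 ± 0.09), and over the list alone 1 rose and 8 fell. Without OA 8 weeks replicate 1 the adjusted p of the unfolded protein response and secretion list was 0.0703.

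Of 20 inflammatory cytokines and NF-kB targets, Nfkbiz rose (1.51 ± 0.29) and 0 fell, with 2 and 0 adjusted over the list alone, the other being the cyclooxygenase 2 gene Ptgs2 (1.19 ± 0.30). The list was higher (median 0.12, adjusted p = 0.0397; adjusted p = 0.497 with an estimated correlation; fry 0.265). This call ended without OA 8 weeks replicate 2 (0.119), OA 8 weeks replicate 3 (0.114), sham 8 weeks replicate 1 (0.507) or sham 2 weeks replicate 3 (0.0579), and with the replicate number as a block (0.0573), all for the inflammatory cytokines and NF-kB targets. Of 12 chemokines and receptors, the receptor gene Cxcr4 fell (-2.20 ± 0.47) and 0 rose, with 2 higher and 3 lower adjusted over the list alone, among them Ccl2 and Ccl7 (0.94 ± 0.26). The chemokine list did not pass (median -0.16, adjusted p = 0.929). Of 17 interferon response genes, 15 were lower and 0 passed over all genes (median -0.56, adjusted p = 0.032; adjusted p = 0.575 with an estimated correlation; fry 0.116). Adjusted over the list alone 1 fell, Ifitm1 (-2.94 ± 0.71). The call of the interferon response list ended without OA 8 weeks replicate 3 (0.113), sham 8 weeks replicate 2 (0.199) or sham 8 weeks replicate 3 (0.126), with the replicate number as a block (0.0573) and with the block within each time (0.0885).

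Of 29 genes of TGF-beta and BMP signalling, the activin gene Inhba rose (1.09 ± 0.20) and 0 fell, with 2 higher and 3 lower adjusted over the list alone (median -0.01, mean 0.03, camera up at adjusted p = 0.701). Of 15 WNT signalling genes 0 passed (median -0.03, mean -0.01, camera up at 0.757), and of 8 endothelin and vasoactive genes 0 passed (median 0.02, mean -0.21, camera up at 0.679).

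Endothelial markers were lower in OA at 8 weeks in 11 of 12 genes (median -0.75, adjusted p = 0.015; adjusted p = 0.497 with an estimated correlation; fry 0.0577), with 0 past limma over all genes and 3 adjusted over the list alone, Kdr (-1.35 ± 0.38), Tek (-2.17 ± 0.64) and Emcn (-2.32 ± 0.73). That call ended without OA 8 weeks replicate 3 (0.0770) or sham 8 weeks replicate 2 (0.199 for the endothelial markers). Of 9 adipocyte markers Cfd fell (median -0.30, adjusted p = 0.701), with 1 higher and 1 lower adjusted over the list alone. Of 11 synovial fibroblast and tendon markers Fap fell (-0.96 ± 0.11), with 2 lower adjusted over the list alone (median 0.01, mean -0.19, camera down at 0.633; the median was under 0 with added quantile normalization). Of 5 nerve and Schwann cell markers Gfap fell, with 2 lower adjusted over the list alone (median 0.01, mean -0.90, camera down at 0.309; fry 0.00318). None passed over all genes among 4 erythroid (median -0.94, adjusted p = 0.105; fry 0.0319), 8 neutrophil and marrow myeloid (median -0.47, 0.663), 3 T and B cell (median -1.78, 0.465), 9 smooth muscle and pericyte (median 0.13, mean -0.14, camera up at 0.686) and 3 mast cell markers (median 0.01, 0.701; under 0 with added quantile normalization). Adjusted over the list alone, 2 erythroid markers fell, Alas2 (-2.16 ± 0.70) and Hbb (-1.55 ± 0.52).

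At 8 weeks camera called 15 of 33 lists, 5 higher and 10 lower, and 0 with an estimated correlation (smallest adjusted p = 0.253), while fry called 8, ending 9 of the 15 and adding erythroid and nerve and Schwann cell markers. With the muscle level as a covariate, 8 of the 15 list calls ended (adjusted p from 0.108 to 0.399). They were cartilage matrix, matrix proteases, fibrous and repair matrix, interferon response, the cell cycle, the unfolded protein response and secretion, endothelial markers and skeletal muscle markers. The last of these is no test, since the covariate is the mean level of that list. Array weights ended the calls of cartilage matrix, the inflammatory cytokines and NF-kB targets and the unfolded protein response and secretion (0.0540 to 0.242), as did leaving out both number 1 arrays (0.151 to 0.337). Camera on ranks ended those of cartilage matrix, the EGF family and the inflammatory cytokines and NF-kB targets (0.0509 to 0.114). No filter ended the inflammatory call (0.0687), the filter at log2 6 the interferon response call (0.0898), and quantile normalization the calls of cartilage matrix and matrix proteases (0.0569 to 0.130). The 3 OA arrays did not overlap the 3 sham arrays for 3998 probe sets (25.1%, against 10% by chance for independent arrays), and 255 of the 552 called probe sets differed at least 2-fold. For OA against sham at 8 weeks the count of 552 became 979 without sham 8 weeks replicate 1, 110 without sham 8 weeks replicate 3, 132 without sham 8 weeks replicate 2, 230 without OA 8 weeks replicate 2, 355 without OA 2 weeks replicate 1 and 358 without sham 2 weeks replicate 1. With arrays of the same number and time as a block it was 1037, of which 474 were among the 552. A total of 91 of the 552 passed with each of the 6 arrays of 8 weeks left out in turn. The calls of Pltp, Clec4a and Cldn11 ended without OA 8 weeks replicate 2 (adjusted p from 0.0543 to 0.0711), sham 8 weeks replicate 2 or sham 8 weeks replicate 3. Those of Mmp13, Ppargc1a and Anks1b ended without sham 8 weeks replicate 2 (all 6 genes from 0.0528 to 0.0834) or sham 8 weeks replicate 3 (0.0553 to 0.0889). The call of Cldn11 also ended with no filter (0.0567). The muscle covariate ended 11 of the 17 calls followed through the alternatives, those of these 6 genes and of Cfd, Cpxm1, G0s2, Nr3c2 and Nr4a2 (0.0528 to 0.229). The differences kept their direction with it, at -4.72 for Cfd, -5.24 for Pltp, -4.40 for Cldn11, -3.57 for Cpxm1, -2.62 for Clec4a, -1.62 for Mmp13, 3.41 for Anks1b, 2.59 for Ppargc1a, 2.44 for Nr4a2, 2.43 for Nr3c2 and 2.03 for G0s2. With only the 6 arrays compared, which leaves the differences as they are, 12 ended, those of the same genes except Cpxm1, with Gfap and Rassf4 added (0.0672 to 0.146).

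The comparison at 2 weeks addressed whether OA cartilage differs from sham soon after surgery. No gene passed the limma test (smallest adjusted p = 0.868). The genes of the cell cycle were higher in OA in 30 of 30 cases (median 0.44), and sham 2 weeks replicate 3 had a large part in this. The mean level of the cell cycle genes, centred within each time, was -0.82 in that array, 0.09 and 0.06 in the other 2 sham arrays and 0.33, 0.37 and -0.04 in the OA arrays. Without that array the median fell to 0.14. Mcm4 differed by 0.43 ± 0.18 and Pcna by 0.24 ± 0.11. Marrow-type granule genes were higher in 8 of 8 cases (median 2.23), with the antimicrobial peptide genes Camp at 2.52 ± 0.92 and Defa5 at 2.28 ± 1.11. Immediate early and heat shock genes were lower in 19 of 22 cases (median -0.23, and -0.10 for the immediate early and heat shock genes without sham 2 weeks replicate 3), with Fos at -0.82 ± 0.26 and Ier2 at -0.32 ± 0.12. Tgfa differed by 0.10 ± 0.15, Mmp13 by -0.04 ± 0.46 and Ccl2 by 0.68 ± 1.31.

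Camera called these 3 lists at 2 weeks, the cell cycle higher (adjusted p = 3.8e-10; adjusted p = 0.757 with an estimated correlation), the neutrophil and marrow myeloid markers higher (3.43e-07; adjusted p = 0.364 with an estimated correlation) and the immediate early and heat shock genes lower (0.00083; adjusted p = 0.364 with an estimated correlation). It also called the unfolded protein response and secretion genes lower, 22 of 26 of them (median -0.07, adjusted p = 0.0063; adjusted p = 0.933 with an estimated correlation), with Pdia4 at -0.32 ± 0.15 and Asns at -0.54 ± 0.26. Fry called 0 lists (smallest adjusted p = 0.993), and 0 genes of any list passed over all genes or adjusted over the list alone. Fry and the estimated-correlation test were run without pairing arrays of the same number. The neutrophil and marrow myeloid level, looked at after the results were seen, was -0.02, 1.72 and 1.01 in OA arrays 1 to 3. In sham arrays 1 to 3 it was -1.99, 0.05 and -0.76. Without sham 2 weeks replicate 3 the adjusted p was 0.0503 for the cell cycle and for the immediate early and heat shock genes, which also lost their call without OA 2 weeks replicate 3 (0.128). Camera called 7 lists without sham 2 weeks replicate 3, in place of 4.

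The other 29 lists did not pass camera at 2 weeks. Fibrous and repair matrix genes were lower in 37 of 46 cases (median -0.13, adjusted p = 0.0509) and endothelial markers in 11 of 12 (median -0.27, 0.183). Erythroid markers (median 0.44, 0.123), EGF family genes (median -0.07, 0.850), ERK targets (median -0.13, 0.345) and matrix proteases (median -0.07, 0.393) did not pass either. The medians were -0.00214 for cartilage matrix (0.850), 0.05 for hypertrophy and mineralization (0.408), -0.20 for superficial zone (0.581), -0.06 for hypoxia and glycolysis (0.345), 0.01 for TGF-beta and BMP signalling (0.987), -0.12 for macrophage markers (0.426), 0.04 for osteoblast and osteocyte markers (0.709) and 0.23 for skeletal muscle markers (0.850). They were 0.01 for T and B cell markers (0.850), 0.03 for smooth muscle and pericyte markers (0.850), -0.13 for adipocyte markers (0.850), -0.11 for synovial fibroblast and tendon markers (0.581), -0.02 for mast cell markers (0.850) and 0.10 for nerve and Schwann cell markers (0.850). Median, mean and camera differed in sign for chondrocyte transcription factors and receptors (-0.02, 0.03, up), protease inhibitors (-0.03, 0.05, up), inflammatory cytokines and NF-kB targets (-0.02, 0.03, up), interferon response (-0.04, 0.06, up) and oxidative phosphorylation (-0.00470, 0.01, up), each at adjusted p = 0.850. With array medians equalized, the medians of cartilage matrix, chondrocyte factors, protease inhibitors, inflammatory cytokines, oxidative phosphorylation and mast cell markers at 2 weeks lay above 0. They also differed for chemokines and receptors (-0.06, 0.08, down, 0.979), WNT signalling (-0.04, -0.05, up, 0.850), endothelin and vasoactive signalling (0.02, -0.18, up, 0.863) and osteoclast markers (-0.20, 0.07, down, 0.692).

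The genes with the smallest unadjusted p at 2 weeks, none of which passed, were Fam107b (0.59 ± 0.10), Gnb3 (0.70 ± 0.15), the MYC target Cdca7 (0.60 ± 0.14) and the eosinophil granule gene Prg2 (3.43 ± 0.81) among those higher in OA. Eogt (-1.15 ± 0.26), Rhobtb1 (-0.41 ± 0.11), Zfp532 (-0.43 ± 0.12) and Mettl2 (-0.86 ± 0.24) were lower in OA. Among the genes chosen in advance, Egfr differed by -0.21 ± 0.46, Adamts5 by -0.25 ± 0.50, Col2a1 by 0.04 ± 0.08, Acan by 0.07 ± 0.11 and Col10a1 by 0.24 ± 0.12. The limma count was 0 of 15934 probe sets, with 269 at an unadjusted limma p under 0.05 against 797 by chance, and 27 of 28 alternatives also gave 0. A total of 857 probe sets (5.38%) did not overlap between the groups, against 10% by chance. Both chance values take the arrays as independent. The 269 also rest on a spread shared with the 8-week arrays. Where those arrays varied more, the limma p-values at 2 weeks tend to be too large. Arrays of the same number deviated together from their group means at 2 weeks (correlations 0.33, 0.36 and 0.53) and at 8 weeks (0.24, 0.24 and 0.12). OA and sham arrays of different numbers lay between -0.38 and 0.07 at 2 weeks and between -0.27 and 0.14 at 8 weeks. Sham arrays of different numbers and times reached 0.64, so such values also arise without pairing. If the arrays are paired, the number and share that arise without any OA effect are lower. The median half-width of the 95% interval of a difference was 0.37. Without OA 2 weeks replicate 1, 1 probe set passed, which carries no gene symbol here.

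**Figure D3:**
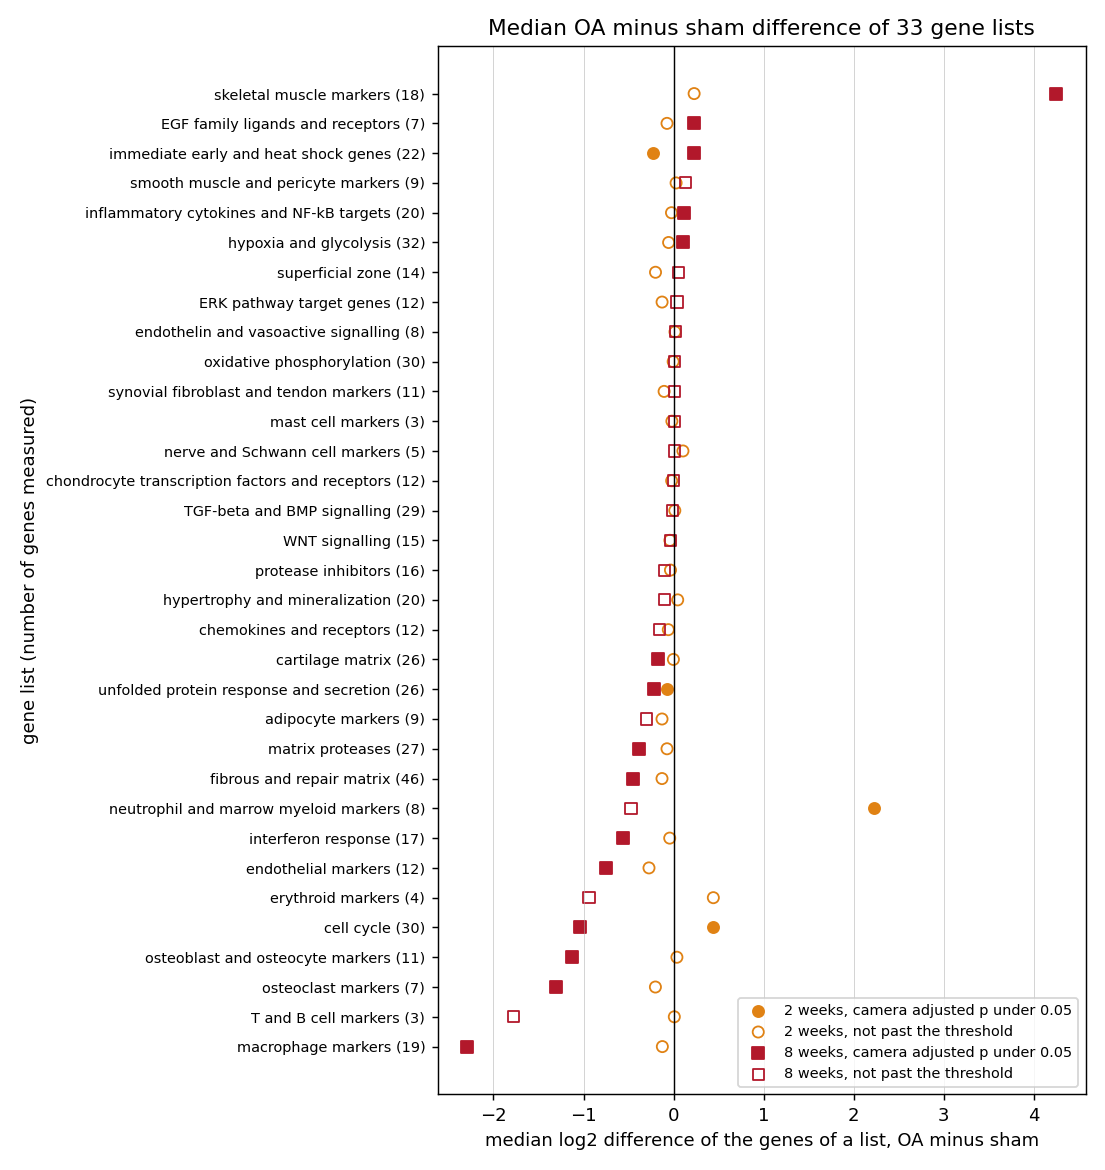
Median log2 difference, OA minus sham, of the genes of each of the 33 lists at 2 weeks (circles) and 8 weeks (squares), with the number of measured genes in brackets and filled symbols where camera with its preset correlation passed. Macrophage markers had a median of -2.29 at 8 weeks and -0.12 at 2 weeks, and the cell cycle list -1.04 and 0.44; no call held with an estimated correlation.

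The interaction asked whether the OA difference itself changed from 2 to 8 weeks. The OA difference of Tgfa was larger at 8 weeks by 2.92 ± 0.21 (adjusted p = 0.00102), that of Itga8 by 4.44 ± 0.41 (both 2-week means under log2 4, at 3.28 and 3.32, so its 2-week difference and this size are not exact), Fez1 by 2.23 ± 0.21, Lhfpl3 by 2.21 ± 0.28 and Mmp3 by 1.39 ± 0.20. It was lower at 8 weeks for Cd68 (-5.94 ± 0.63), Gfap (-4.43 ± 0.66), the cathepsin gene Ctsz (-3.42 ± 0.48), Mfap2 (-2.35 ± 0.33) and Enc1 (-2.17 ± 0.21). Sham levels also differed between the times for some of these, with Tgfa changed by -1.40 ± 0.15 and Mmp3 by -1.37 ± 0.14 from 2 to 8 weeks. The OA means of Mmp3 were 14.91 at 2 weeks and 14.93 at 8 weeks. In these values the sham level of Mmp3 was lower at 8 weeks and its OA level was not. Time and any separate processing of the 2 times stand together. Whether its interaction came from a lower sham or a higher OA level therefore cannot be told. A total of 22 probe sets passed, 10 higher and 12 lower, for 15 genes. Averaged over the probe sets of a gene, Tgfa no longer passed (adjusted p = 0.421), the sole alternative of those run in which it did not.

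Camera called 12 lists in the interaction, 4 higher and 8 lower. Fry gave 0.00349 for the EGF family, 0.0299 for immediate early and heat shock genes, 0.0378 for erythroid, 0.0266 for osteoblast and osteocyte and for osteoclast markers, and 0.0975 to 0.414 for the other 7. With the muscle covariate the fibrous, interferon and erythroid calls ended (0.151 to 0.972), apart from that of skeletal muscle, which such a covariate ends by construction. The erythroid and interferon calls ended with the block within each time (0.124 to 0.126), the planned block (0.0593 to 0.0953) and no filter (0.0702 to 0.0704), and with the EGF family call on ranks (0.0760 to 0.0859). Quantile normalization ended the fibrous, interferon and erythroid calls (0.0554 to 0.120). Array weights (0.0685 to 0.215) and leaving out both number 1 arrays (0.0541) ended the fibrous and erythroid calls, and the filter at log2 6 (0.135) or equalized medians (0.0735) the interferon call. Higher were the EGF family (median 0.38, adjusted p = 0.000681; adjusted p = 0.151 with an estimated correlation), immediate early and heat shock genes (0.47, 2.76e-05; adjusted p = 0.151 with an estimated correlation), hypoxia and glycolysis (0.16, 0.000104; adjusted p = 0.353 with an estimated correlation) and skeletal muscle markers (3.85, 6.96e-06; adjusted p = 0.460 with an estimated correlation). Lower were the cell cycle (-1.56, 8.38e-11; adjusted p = 0.394 with an estimated correlation), macrophage markers (-2.05, 1.47e-07; adjusted p = 0.460 with an estimated correlation), osteoblast and osteocyte markers (-1.17, 2.83e-06; adjusted p = 0.151 with an estimated correlation) and osteoclast markers (-2.13, 2.76e-05; adjusted p = 0.247 with an estimated correlation). Neutrophil and marrow myeloid markers (-2.66, 0.00655; adjusted p = 0.460 with an estimated correlation), erythroid markers (-1.38, 0.0304; adjusted p = 0.247 with an estimated correlation), fibrous and repair matrix genes (-0.31, 0.0159; adjusted p = 0.611 with an estimated correlation) and interferon response genes (-0.33, 0.0447; adjusted p = 0.611 with an estimated correlation) were lower as well. Left out 1 at a time, arrays ended the calls of erythroid markers (OA 2 weeks replicate 2, OA 8 weeks replicate 1 or sham 2 weeks replicate 1, up to 0.182) and neutrophil and marrow myeloid markers (OA 2 weeks replicate 2 or sham 2 weeks replicate 1, up to 0.146). The fibrous list, whose direction turned with the muscle level as a covariate (adjusted p = 0.972), lost its call without OA 2 weeks replicate 2, OA 8 weeks replicate 1, sham 2 weeks replicate 3 or sham 8 weeks replicate 2 (up to 0.304). The interferon list lost its call without OA 2 weeks replicate 2, OA 8 weeks replicate 3, sham 2 weeks replicate 1, sham 2 weeks replicate 3, sham 8 weeks replicate 2 or sham 8 weeks replicate 3 (up to 0.292).

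The interaction count of 22 became 14, 8 and 8 without OA 2 weeks replicate 1, 2 or 3, 8, 7 and 9 without sham 2 weeks replicate 1, 2 or 3, 52 and 40 without OA 8 weeks replicate 1 or 3, and 80, 7 and 10 without sham 8 weeks replicate 1, 2 or 3. It was 67 with the replicate block within each time, where Gfap and Mmp3 did not pass (0.0613 and 0.0692; 0.0675 to 0.0772 with the planned block), and 12 with the muscle covariate, where Ctsz, Gfap, Mfap2 and Mmp3 did not pass (0.0518 to 0.178), at differences of -2.96, -3.80, -1.88 and 1.49. With no filter Ctsz, Gfap, Lhfpl3, Mfap2 and Mmp3 did not pass (0.0612 to 0.0940). Leaving out an array of 2 weeks, OA 8 weeks replicate 2, sham 8 weeks replicate 2 or sham 8 weeks replicate 3 ended the calls of Ctsz, Gfap, Mfap2 and Mmp3. The call of Lhfpl3 also ended without OA 2 weeks replicate 2 or 3, any sham array of 2 weeks, or sham 8 weeks replicate 2 or 3. The adjusted p of these ended calls lay between 0.0539 and 0.135.

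**Figure D4:**
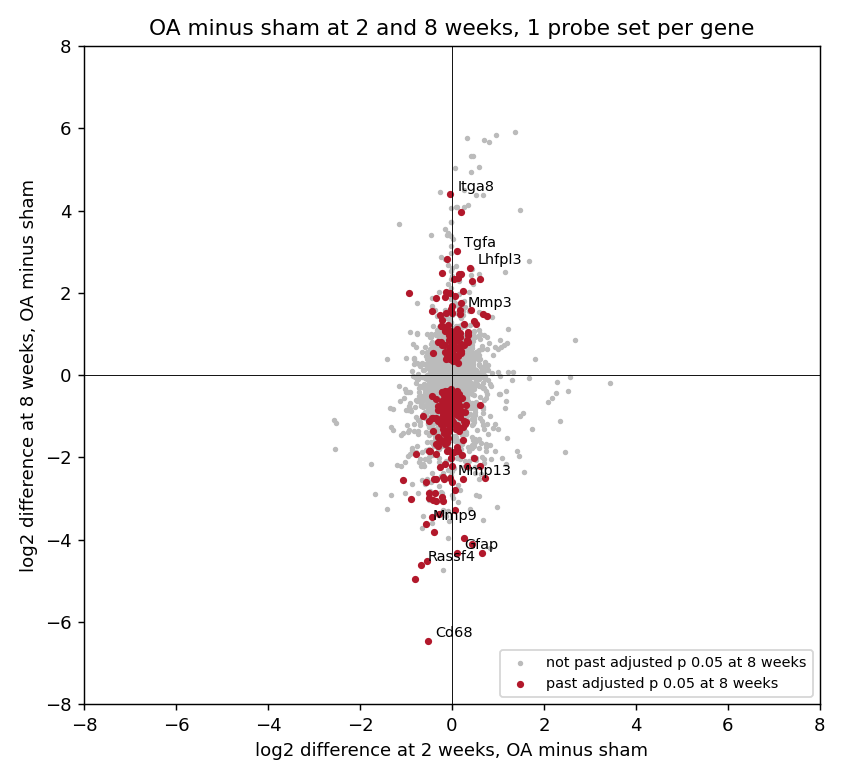
Log2 difference between OA and sham at 2 weeks (horizontal axis) and at 8 weeks (vertical axis) for 9247 genes (points, 1 probe set per gene), with genes past an adjusted p of 0.05 at 8 weeks in red. Cd68 lay at -6.46 at 8 weeks and -0.52 at 2 weeks, and Tgfa at 3.02 and 0.10.

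Across the 15934 probe sets, the OA differences at 2 and 8 weeks correlated with Pearson r = 0.13 and Spearman rho = 0.0856. Probe sets are not independent replicates, and 184 of 400 assignments of the OA and sham labels within each time (46%) gave an r as large in size; these assignments, too, take arrays of the same number as independent. Of the 552 probe sets called at 8 weeks, 335 (60.7%) had the same direction at 2 weeks, with a median size of 0.12 at 2 weeks and 0.92 at 8 weeks. The correlation was 0.0240, 0.0388 and 0.253 without sham 2 weeks replicate 1, 2 or 3.

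The average over both times asked which genes differed between OA and sham in the mean of the 2 differences. It does not show a difference at each time, since no gene passed at 2 weeks, and Lhfpl3 (0.39 at 2 weeks and 2.60 at 8 weeks) and Ctsz (-0.39 and -3.81) also passed the interaction. Lhfpl3 rose 2.83-fold (adjusted p = 0.00267), the proton pump gene Atp6v0a4 by 1.10 ± 0.17 on the log2 scale and Ssbp2 by 0.69 ± 0.08. Rassf4 fell by 2.65 ± 0.33, Ctsz by 2.10 ± 0.24, Mmp9 by 2.10 ± 0.32, and Phgdh, the first enzyme of serine synthesis, by 1.80 ± 0.30. Laptm5 (-1.45 ± 0.22), C1qtnf2 (-0.72 ± 0.11), the cholesterol exporter gene Abcg1 (-0.71 ± 0.07) and Sec22a (-0.32 ± 0.05) fell as well. A further 4 genes did not pass, Slc22a5 (0.66 ± 0.12), Vamp1 (0.75 ± 0.14), Lrif1 (0.49 ± 0.09) and the clock gene Per3 (0.89 ± 0.17). A total of 58 probe sets passed, 21 higher and 37 lower, for 41 genes. The OA arrays lay apart from the sham arrays at both times and in the same direction for 150 probe sets (0.941%). The share that arises by chance was not computed for this count.

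Camera called 11 lists on average over both times, 3 higher and 8 lower, 0 with an estimated correlation (smallest adjusted p = 0.457). Fry gave 0.0104 for the EGF family, 0.0277 for osteoblast and osteocyte and for osteoclast markers, and 0.0607 to 0.374 for the other 8. With the muscle covariate 4 calls ended (0.161 to 0.373), those of cartilage matrix, proteases and fibrous matrix and, by construction, that of skeletal muscle. The EGF family call ended with the block within each time (0.0515) and the mean of a gene's probe sets (0.0634), and the cartilage matrix call with quantile normalization (0.0643). Both ended with array weights (0.0781 to 0.388) and on ranks (0.0742 to 0.226). Leaving out both number 1 arrays ended the cartilage matrix and hypoxia calls (0.0509 to 0.358). Higher were EGF family genes (median 0.11, adjusted p = 0.0145; adjusted p = 0.457 with an estimated correlation), hypoxia and glycolysis genes (0.02, 0.0154; 0.633 with an estimated correlation) and skeletal muscle markers (2.17, 9.21e-06; 0.604 with an estimated correlation). Lower were macrophage markers (-1.19, 4.71e-08; 0.604 with an estimated correlation), osteoblast and osteocyte markers (-0.63, 8.83e-05; 0.457 with an estimated correlation), osteoclast markers (-0.76, 0.000153; 0.561 with an estimated correlation) and endothelial markers (-0.51, 0.00619; 0.604 with an estimated correlation). Fibrous and repair matrix genes (-0.30, 3.8e-05; 0.604 with an estimated correlation), unfolded protein response and secretion genes (-0.16, 0.000285; 0.604 with an estimated correlation), matrix proteases (-0.22, 0.0145; 0.633 with an estimated correlation) and cartilage matrix genes (-0.09, 0.0472; 0.633 with an estimated correlation) were lower as well. Of these 11 calls, 6 held with each of the 12 arrays left out in turn; EGF family (up to 0.0792), hypoxia (up to 0.133), endothelial (0.0510), protease (up to 0.191) and cartilage matrix (up to 0.218) calls did not. The arrays concerned were sham 8 weeks replicate 1 and sham 2 weeks replicate 3 for the EGF family, both of these with OA 2 weeks replicate 2 and OA 8 weeks replicate 3 for hypoxia, and sham 8 weeks replicate 2 for the endothelial markers. They were OA 2 weeks replicate 3, OA 8 weeks replicate 1 and sham 8 weeks replicate 2 for the proteases, and all 3 of these with OA 2 weeks replicate 1, sham 2 weeks replicate 3 and sham 8 weeks replicate 1 for the cartilage matrix.

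The averaged count of 58 became 31, 22 and 37 without OA 2 weeks replicate 1, 2 or 3, 19, 26 and 23 without sham 2 weeks replicate 1, 2 or 3, 36 without OA 8 weeks replicate 2, and 181, 22 and 22 without sham 8 weeks replicate 1, 2 or 3. With the replicate block within each time it was 110, although Atp6v0a4, C1qtnf2, Laptm5, Phgdh and Sec22a lost their calls (adjusted p from 0.0505 to 0.0766), all but Atp6v0a4 also with the planned block (0.0527 to 0.0701). The muscle covariate ended the calls of these 5 and of Ctsz, Mmp9 and Rassf4 (0.0521 to 0.228). The differences with it were 0.92 for Atp6v0a4, -0.68 for C1qtnf2, -1.35 for Laptm5, -1.71 for Phgdh, -0.33 for Sec22a, -1.84 for Ctsz, -1.68 for Mmp9 and -2.32 for Rassf4. No filter ended those of Atp6v0a4, C1qtnf2, Laptm5, Mmp9 and Phgdh (0.0687 to 0.104), and the mean of a gene's probe sets those of Ssbp2 and Laptm5 (0.0650 to 0.0688). The other probe set of Ssbp2 differed by 0.25 at 8 weeks (adjusted p = 0.339). Quantile normalization, equalized medians and a variance trend each ended the call of Sec22a (0.0623 to 0.0897). Lhfpl3, Abcg1, Ssbp2, Rassf4 and Ctsz passed with each of the 12 arrays left out. Atp6v0a4, Mmp9, Phgdh, Laptm5, C1qtnf2 and Sec22a lost their calls without any OA array of 2 weeks, sham 2 weeks replicate 1 or 3, or sham 8 weeks replicate 2 (adjusted p from 0.0613 to 0.118), and all but 1 of them without sham 2 weeks replicate 2 or sham 8 weeks replicate 3 (up to 0.123). Laptm5 and Phgdh also lost theirs without any OA array of 8 weeks, Sec22a without the replicate 2 or 3 of these and C1qtnf2 without replicate 2 (0.0526 to 0.0825).

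The comparison of 8 with 2 weeks within sham gave the background of time after surgery in control joints. The chromatin genes Phf1 (3.63 ± 0.07) and Scmh1 (3.96 ± 0.19) and the mitochondrial gene Maip1 (3.34 ± 0.16) rose. The zinc finger gene Znf780b (-5.13 ± 0.12), Megf6 (-4.03 ± 0.33), the myeloid receptor gene Cd33 (-3.82 ± 0.27), the protein kinase gene Prkch (-3.23 ± 0.11) and the endothelial gene Plvap (-3.12 ± 0.13) fell. The muscle genes Atp2a1 (5.59 ± 1.48) and Myoz1 (4.67 ± 1.23) rose with a far larger spread between arrays, and lost their calls without any 1 sham array of 2 weeks or without sham 8 weeks replicate 1, Atp2a1 also without sham 8 weeks replicate 3 (adjusted p from 0.0553 to 0.0880). Atp2a1, Myoz1, Scmh1, Znf780b, Cd33 and Prkch lay under log2 4 at 1 of the times. A total of 2979 probe sets passed, 1984 higher and 995 lower, for 1373 genes, and 5615 (35.2%) did not overlap, against 10% by chance for independent arrays. Of the 2979, 2672 also passed in the same direction from 2 to 8 weeks within OA, against 554 for independent sets. The labels do not say whether the arrays of both times were processed together, so time after surgery, age and processing stand together in this comparison.

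Camera called 3 lists from 2 to 8 weeks within sham, all lower. Endothelial markers were lower in 10 of 12 genes (median -0.83, adjusted p = 0.000221; adjusted p = 0.633 with an estimated correlation; fry 0.00025), with Flt4 at -2.07 ± 0.08 and Egfl7 at -1.47 ± 0.10. Interferon response genes (median -0.48, adjusted p = 0.036; adjusted p = 0.891 with an estimated correlation; fry 0.178) included Oasl (-1.44 ± 0.12) and Mx2 (-1.94 ± 0.22). Cell cycle genes (median -0.08, adjusted p = 0.0397; adjusted p = 0.891 with an estimated correlation; fry 0.178) included Birc5 (-2.81 ± 0.08) and Aurkb (-2.06 ± 0.23), while 14 of the 30 were higher. Both of these calls ended with the block within each time (0.281 and 0.560), quantile normalization (0.0630 to 0.0909), equalized medians (0.149), array weights (0.122) and without both number 1 arrays of 8 weeks (0.716 to 0.767). The cell cycle call also ended with no filter (0.103), the filter at log2 6 (0.536) and the mean of a gene's probe sets (0.0751). The interferon and the cell cycle call ended without sham 2 weeks replicate 1, sham 2 weeks replicate 2 or sham 8 weeks replicate 1 (up to 0.655), the cell cycle call also without OA 8 weeks replicate 1 or OA 8 weeks replicate 2. The number of called lists was 1 without sham 2 weeks replicate 1, sham 2 weeks replicate 2 or sham 8 weeks replicate 1, 6 without sham 2 weeks replicate 3 and 5 without sham 8 weeks replicate 2.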

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

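The tests of the marker genes, of the shift between times and of the muscle genes were chosen after the results were seen, whereas the counts over other splits of the arrays were planned.

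The OA difference at 8 weeks departed from that at 2 weeks in 15 genes, singled out by the interaction test. It was larger at 8 weeks for Itga8 (4.44, with both 2-week means under log2 4), Tgfa (2.92), Fez1 (2.23), Lhfpl3 (2.21), Mmp3 (1.39) and Stard13 (1.12). It was lower for Cdca7 (-1.33), Foxs1 (-1.45), Srpx (-1.82), Ccdc88c (-1.97), Enc1 (-2.17), Mfap2 (-2.35), Ctsz (-3.42), Gfap (-4.43) and Cd68 (-5.94); the 8-week OA means of Foxs1 and Cd68 lay under log2 4, so these sizes are not exact. Camera on the same interaction singled out 12 gene lists, given here with the median over their genes. These were EGF family genes (0.38), hypoxia and glycolysis (0.16), immediate early and heat shock genes (0.47) and skeletal muscle markers (3.85), all higher. Lower were fibrous and repair matrix (-0.31), interferon response (-0.33), the cell cycle (-1.56), macrophage (-2.05), neutrophil and marrow myeloid (-2.66), erythroid (-1.38), osteoblast and osteocyte (-1.17) and osteoclast markers (-2.13). None of the 12 list calls held with an estimated correlation (smallest adjusted p = 0.151), and fry ended 7 of them.

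For the interaction, 9 of 100 splits within each time, the real one included, gave at least the 22 probe sets found, and the highest of the other splits gave 101. Besides the real one, 9 splits kept the real 8-week groups and so carried the 8-week difference itself. All 8 others that gave as many were among these, and the highest count with other 8-week groups was 1. The share therefore cannot decide about chance, which is not excluded for this count. For the average over both times, 3 of 100 splits gave at least 58, and the highest other split gave 171. Both others that gave as many kept the real 8-week groups, and the highest count with other 8-week groups was 1. The share thus rests on the 8-week arrays, where splits are too few, and whether chance can be excluded for the average is left open. Within 1 time there are 10 splits, too few for a share under 0.05. At 8 weeks 1 of 10 splits gave 552, the real one, and the highest other gave 0. At 2 weeks 10 of 10 gave at least the real 0, and the highest other gave 3. For time within sham 1 of 10 gave 2979, the real one, and the highest other gave 2. Arrays of the same number tended to deviate together within a time, so the splits that part the 3 pairs were also compared, of which there are 4, and the highest of these other than the real one gave 0 at 2 and at 8 weeks.

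Macrophage, osteoclast and bone markers were lower in OA at 8 weeks (median -2.05 over 37 genes). Dilution by muscle RNA would lower cartilage genes as much, where their values can show a fall. The 38 cartilage matrix and chondrocyte genes had a median of -0.11 (middle 50% from -0.50 to 0.09). The macrophage markers had a median of -2.29 (-3.04 to -1.80). This argues against dilution as the whole cause only for cartilage genes that lie below the top of the scale. Col2a1, for example, read close to the highest values of the arrays, where a fall may be compressed. How many of the 38 genes this concerns was not tested. A median of -1.59 without sham 8 weeks replicate 3, the smallest with 1 of the 6 arrays left out, argues against 1 array as the source of the whole pattern. The sham arrays differed among themselves, with a macrophage level of -0.47 in replicate 1 against 1.80 and 2.37 in the others. Leaving out 1 array at a time cannot tell which of these is typical of sham. A smaller share of bone marrow in the OA samples cannot be told apart from other causes, since 15 other marrow genes had a median of -0.56 and a middle 50% (-1.81 to -0.19) that just overlaps that of the macrophage markers; a first version of this rule, which compared the lower quartile of -1.81 with the macrophage median of -2.29, spoke against marrow and was loosened after the value was seen. Fewer such cells in OA cartilage or attached bone, and lower expression per cell, may both underlie the pattern and were not tested.

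Levels shifted between the 2-week and the 8-week arrays in both surgeries. Of 14232 probe sets under log2 4 on all 12 arrays, 27.0% had the 6 arrays of 1 time apart from the 6 of the other, against 0.216% by chance, and the OA and sham shifts correlated at 0.937 across probe sets, which are not independent. Of 47 probe sets with little spread and a sham shift over 1, 47 had an OA shift within 0.2 of it. These values are consistent with arrays of both times processed apart, which the labels do not state. Age and time after surgery stay open, were not tested, and coincide with any such processing.

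Skeletal muscle markers were higher in OA at 8 weeks (median 4.25). If muscle tissue in the samples were the source, its genes should vary together from array to array. Their mean pairwise correlation around the group means was 0.651. This lay between the bounds of 0.7 and 0.3, which were set after the results were seen. The test therefore does not decide whether muscle tissue was the source, and it does not weigh other sources. Without OA 8 weeks replicate 1 the median was 2.63, the smallest with 1 of the 6 arrays left out, which stayed above the bound set for the test. The muscle level varied widely between arrays, however (SD 2.45 in OA and 2.33 in sham, two-sided exact permutation p = 0.2). Whether 1 array is out of place is therefore left open. OA 8 weeks replicate 1 had the highest muscle level and also differed from the others in its control probe sets (Gapdh 0.885 against 1.24 to 1.47), and whether these go together was not tested. No biological explanation was tested.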

How the results depend on the processing

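The replicate block within each time, the fit without both number 1 arrays of 8 weeks and the muscle covariate were chosen after seeing the data. Named genes picked by the rule for the largest changes, and those chosen in advance, were followed through the alternatives, and members named for a list were not. No call so followed changed direction. Among followed genes that did not pass, the difference changed sign in at least 1 alternative for Tgfa, Egfr, Ccl2, Mmp13, Adamts5 and Col2a1 at 2 weeks and for Egfr, Adamts5 and Col10a1 at 8 weeks.

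The count at 2 weeks was 0 in 27 of 28 alternatives, and 0 to 1 with 1 array left out. Of 17 followed calls at 8 weeks, 4 held under every alternative run (Itga8, Tgfa, Lhfpl3 and Cd68), as did 2 of 11 for the average (Lhfpl3 and Abcg1), 4 of 10 for the interaction (Itga8, Fez1, Cd68 and Enc1) and 8 of 10 for time within sham.

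The count of probe sets for OA against sham at 8 weeks (552) was within 1.5 times in 13 of 28 alternatives. By construction it was 255 at 2-fold or more, 1203 at an adjusted p under 0.1, and 328 or 330 genes with 1 probe set or the mean of the probe sets per gene. It was 362 with no filter, 1567 with array weights, 1037 with the replicate block within each time and 48 with the muscle covariate. With only the 6 arrays compared it was 27, in a fit with fewer residual degrees of freedom and a spread no longer shared with the 2-week arrays. With 1 array left out the count ranged from 110 to 979. Except for the thresholds and the units, the cause was not tested.

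OA against sham averaged over both times (58) gave 23 with no filter, 296 with array weights, 27 at 2-fold or more, 165 at an adjusted p under 0.1, 110 with the block within each time, 222 without both number 1 arrays, 16 with the muscle covariate and 19 to 181 with 1 array left out. The difference between the 8-week and the 2-week OA effect (22) gave 8 with no filter, 39 with quantile normalization, 36 with equalized medians, 130 with array weights, 69 at an adjusted p under 0.1, 14 with the mean of the probe sets, 67 with the block within each time, 130 without both number 1 arrays, 12 with the muscle covariate and 7 to 80 with 1 array left out. The comparison of 8 weeks against 2 weeks within sham (2979) gave 6938 with no filter, 1523 with the filter at log2 6, 1491 at 2-fold or more, 1304 with 1 probe set and 1587 with the mean of the probe sets per gene, and 2428 to 3148 with 1 array left out. Apart from thresholds and units, the cause was not tested.

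With an estimated correlation camera called 0 lists in each of the 5 comparisons. Fry called 0 lists at 2 weeks, 8 at 8 weeks, 4 for the average, 6 for the interaction and 5 for time within sham. It ended 4 of 4, 9 of 15, 8 of 11, 7 of 12 and 2 of 3 of the camera calls, and the calls beyond those it kept were lists that camera did not call. Camera called 7 lists at 2 weeks with array weights and 8 at 8 weeks with the muscle covariate. That covariate ended 8 of 15 list calls at 8 weeks, 4 of 11 for the average and 4 of 12 for the interaction, in each of them that of skeletal muscle by construction. For time within sham it called 5 with the filter at log2 6, 1 with quantile normalization, equalized medians, array weights or without both number 1 arrays, and 6 with the muscle covariate. With 1 array left out, lists called ranged from 3 to 7 at 2 weeks, 11 to 15 at 8 weeks, 9 to 13 for the average, 9 to 14 for the interaction and 1 to 6 for time within sham. The cause was not tested.

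The correlation of the OA effects at 2 and 8 weeks (0.13) was 0.0668 with the muscle covariate and 0.0240 to 0.253 with 1 array left out; the cause was not tested. Signal over background limits genes near the floor, where a fall cannot be measured in full.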

Other observations

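The genes and lists described here and the test of the poly-A controls were chosen after the results were seen; the test of the 3-prime minus 5-prime differences was planned. From 2 to 8 weeks within sham, members of signalling lists moved in both directions. Among WNT genes the receptor gene Fzd1 rose (1.61 ± 0.14), and the transcription factor gene Tcf7 (-1.86 ± 0.28) and the inhibitor gene Sfrp2 (-1.70 ± 0.34) fell. Among TGF-beta and BMP genes the antagonist gene Chrdl1 rose (1.45 ± 0.13) and the inhibitory Smad6 fell (-0.78 ± 0.12). The matrix gene Fbln2 rose (1.71 ± 0.26), and the glycolysis gene Pfkl (-0.90 ± 0.07), the chemokine gene Cx3cl1 (-0.74 ± 0.06) and the macrophage gene Csf1r (-1.91 ± 0.27) fell.

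Time after surgery, age and processing stand together in the sham comparison. Its measured mast cell markers were only Hdc, Tpsb2 and Gata2, which moved in both directions. Fry called 5 lists for time within sham, which camera with an estimated correlation did not. They were mast cell markers (fry adjusted p = 8.58e-06; Hdc -0.94 ± 0.08, Tpsb2 -0.61 ± 0.07, Gata2 0.45 ± 0.09), endothelial markers (0.00025), nerve and Schwann cell markers (0.00183; Prph 0.86 ± 0.10), synovial fibroblast and tendon markers (0.00372; Cd248 -2.30 ± 0.10) and EGF family genes (0.00504; Tgfa -1.40 ± 0.15, Adam17 -0.95 ± 0.14).

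OA 8 weeks replicate 1 had a 3-prime minus 5-prime difference of 0.885 for Gapdh, against 1.24 to 1.47 in the other arrays, of 5.38 for actin, against 7.72 to 8.66, and a mean of 9.95 for the hybridization controls, against 10.7 to 11.5. At 8 weeks the mean OA minus sham difference was -0.195 for the Gapdh measure (two-sided exact permutation p = 0.1, the smallest possible), -1.11 for the actin measure (exact permutation p = 0.3) and -0.381 for the poly-A controls (exact permutation p = 0.1).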
